A study of Mus musculus with 10 samples.

How the data were processed

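Ribosome footprints of 10 libraries were analysed, 2 for each of 5 groups of the mouse embryonic stem cell line E14. Per the labels' protocols, cells of this 129/Ola line were kept on gelatine in serum with LIF, treated briefly with cycloheximide, lysed and digested with RNase I, and monosomes were taken from spin columns. Ribosomal RNA was depleted, a small RNA kit was used for the libraries, and Drosophila spike-ins were added, also per the labels' protocols. Per the submitters' processing notes, Trimmomatic and Bowtie2 were used with the mouse build mm10 (GRCm38) and the Drosophila build dm6 (BDGP6), with no versions or roles given. The deposited table, made by the authors, gives whole-number counts of reads per gene with 1 column per library and no normalization. The sources used here do not state the counting tool, the annotation, the strand setting or how the genes in the table were chosen. Reads of overlapping or antisense genes and of close paralogs, such as Rhox6 and Rhox9 or the members of the Zscan4 cluster, therefore cannot be told apart in these counts.

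Columns were matched to the labels by the library number printed in both. The columns for the Ago knockout carry other replicate numbers than their titles, and the titles' numbers were used. The table held mouse genes alone, so spike-in totals could not serve as library sizes. All 11011 gene identifiers of the table were found in the annotation, and 16 symbols that had been turned into dates were replaced by the symbol given there. Coordinates and 3' UTRs came from GENCODE M21 on GRCm38.

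Counts were analysed in R 4.3.3 with edgeR 4.0.16. Library sizes were scaled by TMM, genes were kept by filterByExpr with the 5 groups, which removed 33 and left 10978, and a quasi-likelihood model with 1 mean per group was fitted to all 10 libraries. This left 5 residual degrees of freedom, with a median prior of 6.69 and a biological coefficient of variation of 0.306. Each knockout was compared with WT, the mean of the 4 knockouts with WT, and each knockout with each other, and p-values were adjusted by Benjamini-Hochberg within each comparison at a threshold of 0.05. All tests were 2-sided. The SD is given between the 2 libraries of a group. The SE was derived from the test, as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. Nothing in the labels says whether replicates came from separate cultures or days, so the p-values measure only the spread between these samples.

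CPM values used the scaled library sizes. A floor of 3 counts, taken over each unscaled total count, corresponded to 0.271 and 0.126 CPM in WT, 0.0371 and 0.605 in Dgcr8, 1.62 and 1.34 in Drosha, 0.552 and 1.71 in Dicer, and 0.213 and 0.0853 in Ago. For a group at 0 counts the fold is a lower bound against 3 counts over the group, and for 1 to 3 counts the ratio of pooled counts has an exact 95% binomial interval. PCR copies are not independent molecules, so these intervals and floors cover counting error only.

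The sets of genes to name were fixed before the data were examined, as were the comparisons, the tests and the alternatives unless stated otherwise. Named were the 5 targeted genes, the 8 genes per direction with the largest change among those past the threshold with at least 20 CPM in the higher group and every knockout library on 1 side of both WT libraries, and up to 4 members of each list with the smallest adjusted p. For genes called in all 4 knockouts up to 10 per direction were named, and for differences between knockouts up to 4 per direction. Symbols of predicted genes were skipped, and some genes that met these rules, though counted among the named genes, are not reported here. In the comparison of Dgcr8 with WT, Smyd1 fell outside the rule because its group mean was under 20 CPM there, and it is named because so few genes passed. The genes shared by Drosha, Dicer and Ago, the genes lost without single libraries, the genes of chromosomes 1, 15 and Y, and the list members given with values beyond the first 4 were chosen after their values were seen.

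The 28 gene lists covered the targeted genes, the small RNA pathway, known miRNA targets, pluripotency, other cell types an embryonic stem cell culture can hold, stress and interferon responses, translation, metabolism, signalling, imprinting and miRNA host genes. They were tested with camera from limma 3.58.1 at a preset correlation of 0.01, over 112 tests, and again with an estimated correlation and with fry. Of the 112 tests 35 passed with the preset correlation, 0 with the estimated one, and 15 with fry, which asks whether members move 1 way on balance. With fry, 12 of the 35 passed, and 72 of 112 passed its test of change in either direction. Median, mean and test had the same sign in all 35, and differed in 20 of the other tests. The count of members adjusted over the list alone applies Benjamini-Hochberg to the members of that list.

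Sites of 14 miRNA seed families were searched as 7mer-m8 matches in the longest annotated 3' UTR of 10932 genes. The list of genes with a site was tested with camera and its median compared with 10000 random lists matched on 3' UTR length and mean expression. The matching was done in Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3, and plots with Matplotlib 3.10.9.

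The 4 comparisons share the WT libraries, which raises correlations and overlaps with no effect at all. Groups without any change were therefore simulated 25 times at the libraries' own depths, with 1 dispersion per gene shared by all 10 libraries. The log2 spread between replicates in fact ran from 0.468 in WT to 1.07 in Drosha, which the simulation does not carry. The simulated correlation, covariance and overlap are given beside the observed ones. The simulated comparisons made 0.40, 0.28, 0.24 and 0.12 calls on average for Dgcr8, Drosha, Dicer and Ago.

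The test was also tried on simulated data. With 100 genes changed 4-fold and 100 changed 2-fold, 60%, 54%, 63% and 68% of the 4-fold changes were recovered in Dgcr8, Drosha, Dicer and Ago, and 4%, 1%, 5% and 5% of the 2-fold changes. False calls were 2 of 66, 5 of 60, 4 of 72 and 6 of 79. Changes of 2-fold were therefore mostly out of reach of the single-gene tests. In the same trial of the seed comparison, a list of unchanged genes lay above the 95% range of its random lists in Ago, so a single median near the edge of that range is weak evidence.

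Alternatives were RLE, total-count and upper-quartile scaling, no filter and a stricter filter of 10 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, a fit to the 2 groups compared only, a test against a 1.5-fold change, blocks for the replicate number and for runs of library numbers, and leaving out each library in turn. Thinning every library to the smallest total and leaving out chromosomes 1, 15 and Y were added after the data were seen. Comparisons of 2 libraries with 2 cannot be split or permuted to a p under 0.05.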

Results

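Ribosome profiling, which sequences the mRNA stretches that ribosomes shield from nuclease, was carried out on 10 libraries of the mouse embryonic stem cell line E14. The cells grew in serum with LIF, a cytokine that holds them undifferentiated. There were 5 groups of 2 libraries, namely WT and lines labelled as knockouts of Dgcr8, Drosha, Dicer, and Ago1 and Ago2 together. Dgcr8 and Drosha cut primary miRNA transcripts in the nucleus, Dicer cuts precursor miRNAs and long double-stranded RNA in the cytoplasm, and Ago proteins hold the small RNAs that silence mRNAs. The stated aim of the series was a record of ribosome occupancy in WT cells and in cells lacking these proteins. No matched mRNA libraries were part of the table, so a change in ribosome footprints includes any change in mRNA amount.

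The table held 11011 genes. Total counts were 11082243 and 23731070 in WT, 80850950 and 4955916 in the libraries labelled Dgcr8 knockout (Dgcr8 libraries), 1854243 and 2230566 in the Drosha knockout, 5432599 and 1754710 in the Dicer knockout, and 14064896 and 35168638 in the Ago knockout. The deepest library had 46.1 times the counts of the shallowest. Across genes, which are not independent replicates, the replicates' log2 CPM correlated with r of 0.977 in WT, 0.928 in Dgcr8, 0.896 in Drosha, 0.952 in Dicer and 0.928 in Ago. The first Dgcr8 library resembled the first WT library (r 0.959) more than its own replicate. Likewise, the first Drosha library was closer to the first Dicer library (r 0.951) than to its replicate. The first Ago library was closer to the first Drosha library (r 0.946) than to its replicate. The second Drosha library had 227 genes at 0 counts, while the first, which was shallower, had 33.

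The targeted genes were read first. Drosha fell in the Drosha knockout from 177 ± 0.283 CPM to 29.4 ± 7.24 CPM (mean ± SD, n = 2 libraries per group throughout), Dicer1 fell in the Dicer knockout from 123 to 18.9 ± 4.42 CPM, and Ago2 fell in the Ago knockout from 81.9 ± 0.0133 to 10.8 ± 5.88 CPM. The log2 fold changes were -2.59 (SE 0.33, adjusted p = 0.0067), -2.72 (SE 0.39, adjusted p = 0.0026) and -2.94 (SE 0.38, adjusted p = 0.0059), all from edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment. Dgcr8 went against its label. It was at 32.9 ± 0.235 CPM in WT and rose to 145 ± 0.568 CPM in the libraries labelled Dgcr8 knockout (log2 2.14, SE 0.26, adjusted p = 0.015), and every direction given for those libraries carries that doubt. Dgcr8 also rose in the Drosha knockout to 183 ± 19.9 CPM (log2 2.48, adjusted p = 0.0028), in the Dicer knockout (log2 1.09, adjusted p = 0.021) and in the Ago knockout (log2 1.07, adjusted p = 0.047). Ago1 was not lower in the Ago knockout, at 27.0 and 10.7 CPM in its 2 libraries and 14.5 CPM in WT (log2 0.37, SE 0.40, adjusted p = 0.67). Ago1 rose in the Drosha knockout to 66.8 ± 8.54 CPM (log2 2.20, adjusted p = 0.022) and in the Dicer knockout to 72.5 ± 11.3 CPM (log2 2.33, adjusted p = 0.0062). Without the second WT library Drosha (adjusted p = 0.098) and Ago2 (0.062) lost their calls in their own knockouts. Dgcr8 lost its call in the libraries labelled for it without the first (0.24) or second (0.44) WT library or the second Dgcr8 library (0.083), with log2 values between 2.14 and 2.15. In the Drosha knockout it lost the call without the first (0.053) or second (0.098) WT library, and in the Dicer and Ago knockouts without either library of WT or of that knockout, and in Ago also without either Dicer library, at adjusted p between 0.065 and 0.42. Total-count scaling also ended the call in Ago (0.060). The labels do not say which part of each gene was deleted, and counts over a whole gene do not show whether a protein was made.

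In GRCm38 coordinates, Dgcr8 (ENSMUSG00000022718) lies on chromosome 16 from 18253948 to 18289246, Drosha (ENSMUSG00000022191) on chromosome 15 from 12824815 to 12935291, and Dicer1 (ENSMUSG00000041415) on chromosome 12 from 104687742 to 104751952. Ago1 (ENSMUSG00000041530) lies on chromosome 4 from 126435012 to 126468583, and Ago2 (ENSMUSG00000036698) on chromosome 15 from 73095844 to 73184935.

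Which footprints differ between WT and the libraries labelled Dgcr8 knockout was the first comparison. Grb10, an imprinted adaptor that restrains growth factor signalling, fell from 524 ± 73.4 to 22.3 ± 17.7 CPM (log2 -4.51, SE 0.56, adjusted p = 0.015), and Myh9, the heavy chain of non-muscle myosin, fell from 587 ± 187 to 97.5 ± 11.7 CPM (log2 -2.59, SE 0.34, adjusted p = 0.019). Lgals3, a galactoside-binding lectin, rose from 16.9 ± 8.55 to 127 ± 50.3 CPM (log2 2.91, SE 0.40, adjusted p = 0.023). Nexmif rose from 13.1 ± 0.731 to 80.9 ± 43.9 CPM (log2 2.62, SE 0.37, adjusted p = 0.025), Dusp27 from 31.5 ± 3.98 to 158 ± 31.8 CPM (log2 2.33, SE 0.32, adjusted p = 0.023), and Crmp1, a neuronal cytoskeletal regulator, from 14.8 ± 1.10 to 59.1 ± 1.60 CPM (log2 2.00, SE 0.30, adjusted p = 0.041). Smyd1, a muscle histone methyltransferase, also rose (log2 4.34). With Dgcr8, these 6 higher and 2 lower genes were all that passed an adjusted p of 0.05 among 10978 tested, while 1077 had an unadjusted p under 0.05. DESeq2 called 160 genes and limma-voom 15.

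Among the gene lists in the libraries labelled Dgcr8 knockout, the integrated stress response, genes switched on by Atf4, fell with a median log2 fold change of -0.96 over 31 genes (camera adjusted p = 4.6e-15, but adjusted p = 0.34 with an estimated correlation). No member of it passed over all genes, and 6 fell when adjusted over the list alone, with Stc2 at -2.84 and Ddit4 at -2.06 among the lower values. Cholesterol synthesis genes fell (24 genes, median -0.65, adjusted p = 2.5e-08, adjusted p = 0.23 with an estimated correlation), with 0 calls over all genes and 6 lower members adjusted over the list alone, and Insig1 stood at -1.52. Imprinted genes rose as a list (17 genes, median 1.27, adjusted p = 0.021, adjusted p = 0.24 with an estimated correlation) although Grb10 fell, and adjusted over the list alone 4 rose and 2 fell, with Peg3 at 1.71 and Impact at 1.41. Glycolysis genes fell (21 genes, median -0.51, adjusted p = 0.00044, adjusted p = 0.44 with an estimated correlation) with 0 members called either way. The knockout targets (5 genes, median 0.42, adjusted p = 0.00014) and the small RNA pathway (19 genes, median 0.29, adjusted p = 0.0025) rose, with adjusted p = 0.24 and adjusted p = 0.29 with an estimated correlation. Dgcr8 was the called member of both, with 2 and 1 higher members adjusted over the list alone. Formative and primed pluripotency genes rose (16 genes, median 0.43, adjusted p = 0.033, adjusted p = 0.72 with an estimated correlation), with 1 higher member adjusted over the list alone and Zic2 at 2.54.

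These Dgcr8 results rested on single libraries. The 8 calls became 2 without the first WT library, 0 without the second WT library, 107 without the first Dgcr8 library, 0 without the second and 3 without the second Dicer library, and 0 of the 7 genes named above by rule kept their call under every alternative. Among the lists, the formative genes lost their call without the second Dgcr8 library (adjusted p = 0.68), the first WT library (0.075) or the second Ago library (0.051). Glycolysis lost it without the first Dgcr8 library (0.19) and the small RNA pathway without the second (0.11), while the imprinted genes lost it without the second Dgcr8 library (0.17), the first WT library (0.069) or the second (0.073).

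Differences between WT and the Drosha knockout came next. Smyd1 rose from 0.175 to 34.1 ± 9.26 CPM (log2 7.57, SE 0.53, adjusted p = 9.7e-05), Msln, a surface glycoprotein of epithelia, rose from 4.27 ± 0.225 to 252 ± 139 CPM (log2 5.88, SE 0.54, adjusted p = 0.0011), and C1qtnf9 rose to 22.7 ± 3.70 CPM (log2 6.76, SE 1.03, adjusted p = 0.011). Cubn, an endocytic receptor of visceral endoderm, fell from 1016 ± 50.6 to 3.76 ± 4.57 CPM (log2 -8.0, SE 1.72, adjusted p = 0.031), and Pdgfra, a growth factor receptor, fell from 144 ± 6.20 to 5.34 ± 2.33 CPM (log2 -4.73, SE 1.09, adjusted p = 0.039). Sox17, an endoderm transcription factor, fell to 2 counts over both Drosha libraries, a WT to knockout ratio of 58.6 with a counting interval of 16.2 to 485, and Gpx3, a secreted peroxidase, fell to 2 counts, a ratio of 56.6 with an interval of 15.6 to 468. Hist1h1t fell to 3 counts, a ratio of 38.1 with an interval of 13 to 185. Lgals3bp (log2 5.41), Cfp (log2 5.32), Tmem92 (log2 5.01), Capn3 (log2 4.83) and Fat2 (log2 4.37) rose as well, and Cemip (log2 -5.13), Flrt3 (log2 -4.39) and Col4a2 (log2 -3.95) fell.

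In the Drosha knockout, interferon and double-stranded RNA response genes rose (18 genes, median 0.78, camera adjusted p = 0.00014, adjusted p = 0.17 with an estimated correlation). Of them 5 rose over all genes and 7 adjusted over the list alone, among them Parp14 (log2 2.20), Irf9 (log2 2.02) and Oas1a (log2 2.27). Trophectoderm markers rose (10 genes, median 1.32, adjusted p = 2.5e-05, adjusted p = 0.17 with an estimated correlation) with 2 calls, the keratins Krt7 (log2 2.27) and Krt18 (log2 1.31), and 7 adjusted over the list alone. Genes of the state resembling the 2-cell embryo rose (4 genes, median 4.54, adjusted p = 0.00033, adjusted p = 0.17 with an estimated correlation). Zscan4d, with 2 counts in WT, rose with a ratio of 175 (interval 45.6 to 1496), Tmem92 was the other call, and 3 members passed when adjusted over the list alone. Known targets of the miR-290 and miR-302 families rose (19 genes, median 0.62, adjusted p = 0.0049, adjusted p = 0.18 with an estimated correlation) with 0 calls over all genes, and 5 rose and 1 fell adjusted over the list alone.

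The small RNA pathway also rose in the Drosha knockout (median 0.38, adjusted p = 0.024, adjusted p = 0.41 with an estimated correlation), with Tnrc6a (log2 1.63), Tnrc6b (log2 1.60), Ago1 and Dgcr8 higher and Drosha lower, and adjusted over the list alone 6 rose and 2 fell. Glycolysis genes fell (median -0.60, adjusted p = 4.8e-05, adjusted p = 0.39 with an estimated correlation), with the lactate exporter Slc16a3 (log2 -2.47) called and 7 lower members adjusted over the list alone. Cholesterol synthesis (median -0.62, adjusted p = 0.0010) and the integrated stress response (median -0.60, adjusted p = 0.0072) fell with 0 members called and 0 adjusted over the list alone, and their values were adjusted p = 0.41 and adjusted p = 0.86 with an estimated correlation. In edgeR, 378 genes changed in the Drosha knockout, 272 of them upward. The 378 calls became 9 without the first WT library, 1 without the second, 162 and 159 without the first and second Drosha libraries, and 237 and 213 without the first and second Dicer libraries. Of 45 named genes called, 4 stayed called without the first WT library and 1 without the second, Smyd1. The small RNA pathway lost its call without the first WT library (adjusted p = 0.13) or the second Drosha library (0.19).

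The Dicer knockout was compared with WT next. Smyd1 rose to 35.5 ± 4.37 CPM (log2 7.62, SE 0.53, adjusted p = 8.7e-05), Msln to 431 ± 91.2 CPM (log2 6.66, SE 0.56, adjusted p = 0.00039), the cytokine Osm from 0.0830 to 26.0 ± 10.2 CPM (log2 7.84, SE 0.97, adjusted p = 0.0018), and Pof1b to 34.8 ± 7.04 CPM (log2 7.98, SE 1.18, adjusted p = 0.0026). C1qtnf9 (log2 7.22), Tmprss3 (log2 7.20) and Cfp (log2 6.48) also rose. Gata6, the transcription factor that starts primitive endoderm, was at 0 counts and fell at least 86.1-fold, and Gpx3, also at 0, fell at least 62.0-fold. Sox17 fell to 1 count, a ratio of 192 with an interval of 34.5 to 7608, and Habp2 fell to 3 counts, a ratio of 89.6 with an interval of 30.6 to 435. Cubn fell to 3.53 ± 0.316 CPM (log2 -8.14, SE 1.71, adjusted p = 0.012), the endocytic adaptor Dab2 fell from 129 ± 47.1 to 1.24 ± 0.199 CPM (log2 -6.63, SE 1.33, adjusted p = 0.010), and Matn3 (log2 -5.97) and Ctsh (log2 -5.88) fell.

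Interferon and double-stranded RNA response genes rose in the Dicer knockout (median 1.24, camera adjusted p = 5.2e-06, adjusted p = 0.17 with an estimated correlation), with 9 of 18 called higher and 10 adjusted over the list alone. Parp14 (log2 3.61), Oas1a (log2 3.12) and Oas2 (log2 2.67), sensors and effectors of antiviral defence, were among them. Known miR-290 and miR-302 targets rose (median 1.07, adjusted p = 0.00024, adjusted p = 0.17 with an estimated correlation), with 6 of 19 called, among them the cell cycle brake Rbl2 (log2 3.03), the Nodal inhibitor Lefty1 (log2 5.28) and Arid4a (log2 1.53). Adjusted over the list alone, 10 rose and 1 fell. Trophectoderm markers rose (median 2.13, adjusted p = 1.3e-06, adjusted p = 0.17 with an estimated correlation), with Krt7, Krt8 (log2 3.09), Krt18 and Krt19 among 6 calls of 10 members and 6 adjusted over the list alone. Genes of the 2-cell-like state rose (median 4.26, adjusted p = 0.0093, adjusted p = 0.24 with an estimated correlation), with 3 of 4 called, 3 adjusted over the list alone, and Zscan4d at a ratio of 153 (interval 40.5 to 1289).

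Epithelial and mesenchymal markers rose in the Dicer knockout (15 genes, median 0.65, adjusted p = 0.0093, adjusted p = 0.45 with an estimated correlation). The 4 called members were the claudins Cldn3 (log2 3.47), Cldn4 (log2 2.13) and Cldn7 (log2 1.86) and the epithelial splicing factor Esrp1 (log2 3.19), with 5 adjusted over the list alone. Glycolysis genes fell (median -0.98, adjusted p = 4.3e-06, adjusted p = 0.31 with an estimated correlation), with 6 of 21 called, such as the glucose transporter Slc2a1 (log2 -1.53) and lactate dehydrogenase Ldhb (log2 -1.51), and 8 adjusted over the list alone. Cholesterol synthesis fell (median -0.58, adjusted p = 0.0041, adjusted p = 0.44 with an estimated correlation) with 4 of 24 called, among them Msmo1 (log2 -1.62), and 6 adjusted over the list alone. Fibroblast markers fell (8 genes, median -1.15, adjusted p = 0.021, adjusted p = 0.33 with an estimated correlation), with Col6a2 (log2 -2.79), Fbln2 (log2 -2.28) and Mmp2 (log2 -2.09) called and 4 adjusted over the list alone. The integrated stress response fell (median -0.60, adjusted p = 0.0499, adjusted p = 0.89 with an estimated correlation), while its 1 called member, Gpt2, rose (log2 1.48), as it did adjusted over the list alone.

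In edgeR, 807 genes rose and 413 fell in the Dicer knockout. The 1220 calls became 359 without the first WT library, 139 without the second, 233 without the first Dicer library and 510 without the second. Of 81 named genes called, 45 stayed called without the first WT library and 27 without the second. Without the second Dicer library, the fibroblast markers (adjusted p = 0.10) and cholesterol synthesis (0.13) lost their calls. The integrated stress response lost its call without that library (0.25), the first WT library (0.068), the first (0.054) or second (0.056) Drosha library, or the first (0.069) or second (0.077) Ago library.

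In the libraries labelled as the knockout of Ago1 and Ago2, of which only Ago2 was lower, Ctcfl, a germline paralog of the insulator protein Ctcf, rose from 1.07 ± 0.476 to 126 ± 79.7 CPM (log2 6.80, SE 0.68, adjusted p = 0.0014) and Smyd1 to 22.9 ± 3.59 CPM (log2 7.0, SE 0.52, adjusted p = 0.00018). Lefty1 rose from 9.02 ± 6.54 to 490 ± 467 CPM (log2 5.79, SE 1.25, adjusted p = 0.033). Creb5 took 0.159% and 0.0529% of counts in WT, 0.195% and 0.0938% in Dgcr8, 0.242% and 0.175% in Drosha, and 0.384% and 1.04% in Dicer. It rose in Ago from 1072 ± 779 to 22615 ± 26125 CPM (log2 4.40, SE 0.97, adjusted p = 0.036), with 0.416% of the counts in the first Ago library and 3.94% in the second. Without the second its log2 value was 1.95 (adjusted p = 0.16), and it also lost its call without the first (0.11) or second (0.35) WT library. Cfp (log2 6.25), Lgals4 (log2 6.19), Tmem92 (log2 5.18) and Msln (log2 4.82) rose too. Cubn fell to 1.77 ± 2.20 CPM (log2 -9.35, SE 1.73, adjusted p = 0.019), Sox17 fell to 2 counts, a ratio of 671 with an interval of 185 to 5545, and Car4, a carbonic anhydrase, fell from 41.7 ± 0.541 to 0.141 ± 0.200 CPM (log2 -8.68, SE 1.08, adjusted p = 0.0046). Habp2 (log2 -8.02), Dab2 (log2 -7.57), Gata6 (log2 -6.93), Klb (log2 -6.23) and Cemip (log2 -5.69) fell as well.

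Interferon and double-stranded RNA response genes rose in the Ago knockout (median 0.66, camera adjusted p = 6.9e-05, adjusted p = 0.17 with an estimated correlation), with 6 of 18 called, among them Oas2 (log2 2.64) and Ifitm1 (log2 2.42), and 6 adjusted over the list alone. Known miR-290 and miR-302 targets rose (median 0.81, adjusted p = 0.0016, adjusted p = 0.17 with an estimated correlation), with Lefty1 and Arid4a (log2 1.40) called, and 9 rose and 1 fell adjusted over the list alone. Genes of the 2-cell-like state rose (median 4.97, adjusted p = 0.00033, adjusted p = 0.17 with an estimated correlation) with 3 of 4 called, 3 adjusted over the list alone, and Zscan4d at a ratio of 236 (interval 65.1 to 1954). The p53 targets fell (22 genes, median -0.35, adjusted p = 0.0069, adjusted p = 0.45 with an estimated correlation), with Phlda3 (log2 -1.77) and Plk2 (log2 -1.93) called and 3 adjusted over the list alone. Glycolysis genes fell (median -0.43, adjusted p = 0.016, adjusted p = 0.65 with an estimated correlation) with 0 calls, while 1 rose and 2 fell adjusted over the list alone. Ribosomal proteins rose (76 genes, median 0.75, adjusted p = 0.00061, adjusted p = 0.80 with an estimated correlation) with 0 members called and 0 adjusted over the list alone, and the list turned downward without the second Ago library (adjusted p = 0.55).

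In edgeR, 217 genes rose and 99 fell in the Ago knockout. The 316 calls became 18 without the first WT library, 3 without the second, 491 and 494 without the first and second Dgcr8 libraries, 209 without the second Dicer library, and 154 and 194 without the first and second Ago libraries. Of 44 named genes called, 9 stayed called without the first WT library and 2 without the second, Smyd1 and Ctcfl. A block for runs of library numbers ended the calls of Bmp4, Col4a2, Creb5, Habp2, Irf9, Klb, Klf4, Plk2 and Tnrc6a. The second Ago library was alone in its run, so with that block the Ago comparison rests on the first Ago library. The p53 targets lost their call without the second Ago library (adjusted p = 0.28), and glycolysis without the first Ago library (0.48) or the second WT library (0.10).

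Primitive endoderm markers, 14 genes of the extraembryonic layer that lines the yolk cavity, had the lowest list medians in all 4 groups. They fell with medians of -1.73 in the libraries labelled Dgcr8 knockout, -3.79 in Drosha, -4.36 in Dicer and -5.06 in Ago (camera adjusted p = 4.9e-12, 1.1e-14, 5.0e-12 and 5.3e-20). With an estimated correlation the values were adjusted p = 0.29, 0.29, 0.31 and 0.23. Over all genes 0, 6, 11 and 10 members fell, and 1, 14, 13 and 14 adjusted over the list alone, such as Cubn, Sox17, Dab2, Lama1 (log2 -4.14 in Dicer) and Col4a1 (log2 -5.11 in Ago). With Gata6 set to its bound the Dicer median was again -4.36. As a sum, the 14 genes stood at 92.9% and 107% of the WT mean in the WT libraries, 60.6% and 23.5% in the Dgcr8 libraries, 31.4% and 23.4% in Drosha, 33.6% and 22.3% in Dicer, and 34.6% and 22.7% in Ago. The abundant members Lamb1, Lamc1 and Sparc made most of what remained, and 0 of the 14 genes were on another list.

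What the knockouts shared was asked next. In all 4, Dgcr8, Dusp27 (log2 2.33, 2.40, 2.58 and 1.58 in Dgcr8, Drosha, Dicer and Ago), Nexmif (log2 2.62, 2.63, 2.73 and 1.82), Lgals3 (log2 2.91, 2.68, 3.62 and 1.97) and Smyd1 (log2 4.34, 7.57, 7.62 and 7.0) rose, and 0 genes fell in edgeR, where the Dgcr8 comparison had 1077 genes at an unadjusted p under 0.05. Independent lists of these sizes would share 0.000216 genes higher in all 4, and 25 simulations with unchanged knockouts and the same WT libraries gave 0. The 5 genes became 0 without either WT library or without the second Dgcr8 library, 52 without the first Dgcr8 library, 1 without the second Dicer library and 2 without the first Ago library. DESeq2 gave 67. In Drosha, Dicer and Ago together, 131 genes rose and 30 fell, where independent lists would share 0.395 and 0.0360 and the simulations gave 0 and 0. These became 5 and 1 without the first WT library, 1 and 0 without the second, 182 and 61, and 182 and 64, without the Dgcr8 libraries, 57 and 7, and 95 and 5, without the Drosha libraries, 67 and 7, and 80 and 10, without the Dicer libraries, and 54 and 15, and 116 and 4, without the Ago libraries. Lgals4, Osm, Cfp, Msln and Pof1b were among those that rose in all of these groups, and Cubn, Sox17, Gpx3, Flrt3, Col4a2 and Col4a1 among those that fell.

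Across genes, the log2 fold changes of Drosha and Dicer correlated with r of 0.81, those of Dicer and Ago with 0.77, and those of Drosha and Ago with 0.73. Dgcr8 correlated with Drosha, Dicer and Ago at 0.61, 0.61 and 0.60. Groups that did not change would have given 0.37, 0.44 and 0.40 for the first pairs and 0.39, 0.43 and 0.50 for those with Dgcr8 from the shared WT libraries alone, by simulation. Without the first Drosha library the correlations of Drosha with Dicer, Ago and Dgcr8 were 0.43, 0.38 and 0.38, near the simulated values. Without the second Dgcr8 library those of Dgcr8 with Dicer and Ago were 0.46 and 0.41, near and below the simulated values. The simulation was not repeated for these cases. Covariances were 0.97, 0.87 and 0.69 for the first pairs and 0.39, 0.47 and 0.37 with Dgcr8, against simulated values of 0.14, 0.12 and 0.12, and of 0.12 for each pair with Dgcr8. Drosha and Dicer shared 248 higher and 79 lower genes (20 and 3.99 for independent lists), Dicer and Ago 184 and 63 (16 and 3.72), and Drosha and Ago 135 and 31 (5.38 and 0.956), where the simulations gave 0 for each. Without the first WT library these pairs shared 7 and 1, 11 and 4, and 5 and 1, and without the second 1 and 0, 1 and 1, and 1 and 0. Without a knockout library, the totals of 327, 247 and 166 became 121 (first Drosha) to 441 (second Dgcr8), 96 (first Dicer) to 369 (first Dgcr8), and 64 (first Drosha) to 258 (second Dgcr8). With 2 WT libraries the controls could not be split between the comparisons, so part of the excess may come from what those libraries share.

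The mean of the 4 labelled knockouts, with the doubt over the Dgcr8 libraries carried along, gave against WT 418 genes higher and 358 lower, among them Smyd1, Lgals3 and Nexmif upward. The 776 calls became 95 without the first WT library, 3 without the second, and 467 and 475 without the first and second Dicer libraries.

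**Figure D1:**
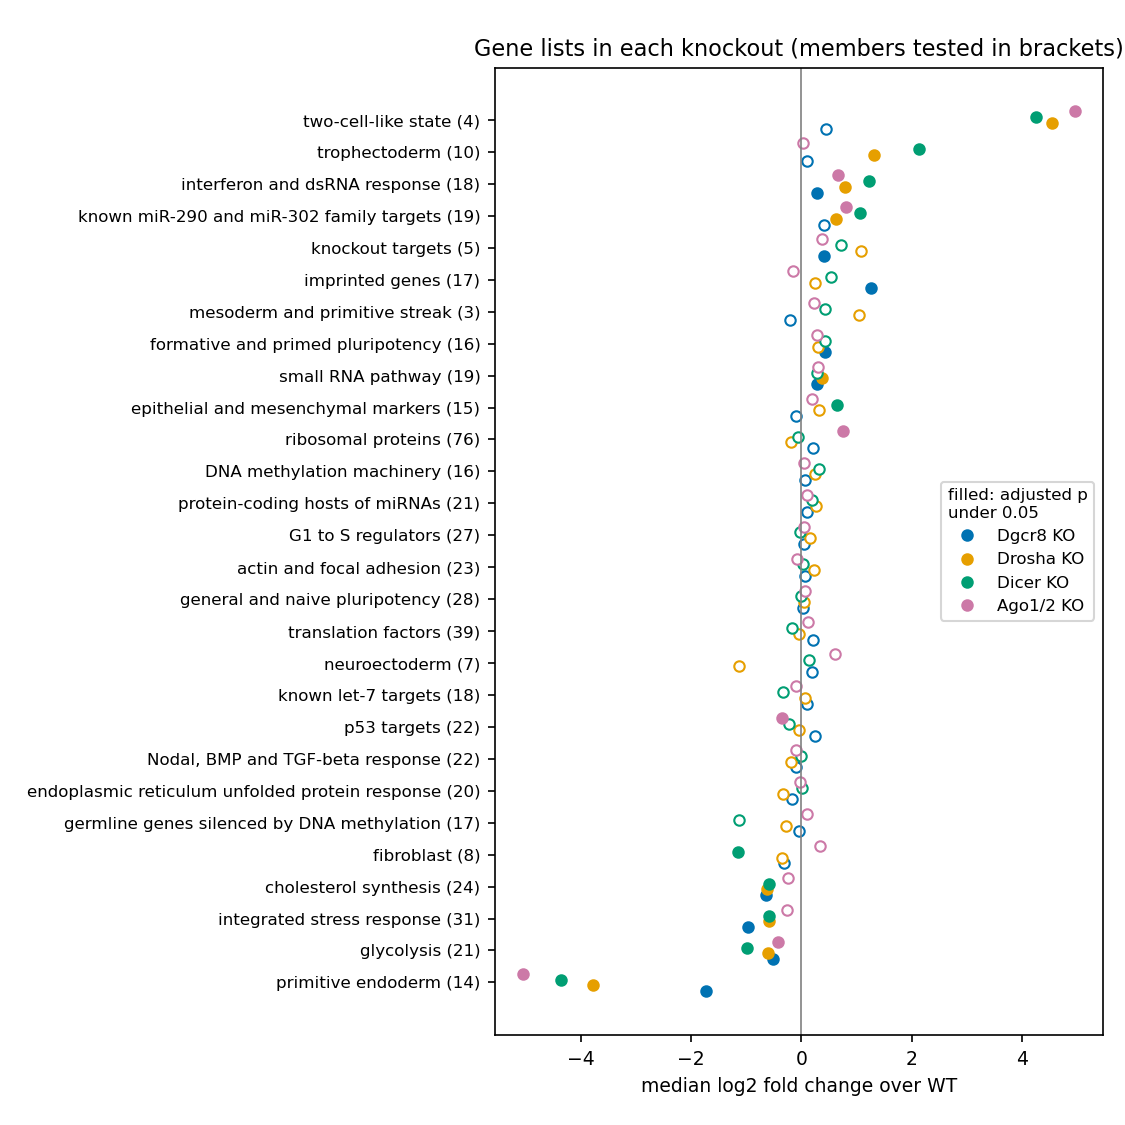
Median log2 fold change of each gene list in each knockout against WT, with list names on the vertical axis and filled circles where the camera adjusted p was under 0.05 and open circles elsewhere. The primitive endoderm list lies furthest to the left and, in Drosha, Dicer and Ago, the 2-cell-like list furthest to the right.

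Lists that passed the test in none of the 4 groups were known let-7 targets, general and naive pluripotency, mesoderm, neuroectoderm, germline genes silenced by DNA methylation, DNA methylation machinery, G1 to S regulators, the endoplasmic reticulum unfolded protein response, translation factors, the Nodal, BMP and TGF-beta response, actin and focal adhesion, and protein-coding hosts of miRNAs. Their medians lay between -1.12 and 1.04 on the log2 scale and their lowest camera adjusted p was 0.090. Single members still changed. Among pluripotency genes Klf2 rose (log2 2.20, 2.36 and 2.11 in Drosha, Dicer and Ago) and Gdf3 rose (log2 1.42, 2.12 and 1.87) while Klf4 fell (log2 -1.52, -2.91 and -1.62), and the mesoderm growth factor Bmp4 fell (log2 -2.24, -2.12 and -1.64). Zic2 of the formative list rose in the same groups (log2 2.85, 3.70 and 3.27), Zbtb38, a binder of methylated DNA, rose (log2 1.85, 2.60 and 2.16), and Rhob, a GTPase of the actin list, rose (log2 2.02, 2.79 and 2.30). Cdkn2a, an inhibitor of the G1 to S step, rose in Drosha (log2 3.18) and Dicer (log2 2.81). Interferon genes also rose as a list in the libraries labelled Dgcr8 knockout (median 0.28, adjusted p = 0.045, adjusted p = 0.41 with an estimated correlation) with 0 calls over all genes and 3 adjusted over the list alone. That call was lost without the first WT library (adjusted p = 0.067), the first Dgcr8 library (0.13), the second Dgcr8 library (0.070), or the first (0.070) or second (0.077) Ago library.

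Whether genes with miRNA sites changed was tested on 10932 genes with an annotated 3' UTR. Genes with a 7mer-m8 site for the miR-290 and miR-302 seed numbered 2044 and had median log2 fold changes of 0.05, 0.12, 0.21 and 0.13 in Dgcr8, Drosha, Dicer and Ago, where 95% of 10000 random lists matched on 3' UTR length and expression lay between 0.0036 and 0.044, -0.0066 and 0.056, 0.037 and 0.098, and 0.00049 and 0.055. Those medians sat at percentiles 99.8, 100, 100 and 100 of the random lists. The related miR-17 seed (1644 genes) sat at percentiles 97.6, 100, 100 and 100. In Dicer, medians for miR-25/92, miR-19, miR-130 and miR-21 lay above the random range as well (percentiles 100, 100, 100 and 98.7), while let-7 sites sat between percentiles 22.3 and 66.4 in the 4 groups and miR-15/16 sites at 21.9 in Dicer. Of 56 camera tests 2 passed, both in Dicer, for miR-290 with miR-302 (adjusted p = 0.041) and miR-17 (adjusted p = 0.040), and adjusted p = 0.999 with an estimated correlation for each. With a block for the replicate number miR-17 stayed past the threshold (adjusted p = 0.0496) and miR-290 with miR-302 did not (adjusted p = 0.059). With 8mer sites 7 tests passed, for miR-290 with miR-302 in Drosha, Dicer and Ago (adjusted p = 0.030, 0.00031 and 0.022), miR-17 in Drosha and Dicer (0.0047 and 0.00031) and miR-25/92 in Drosha and Dicer (0.013 and 0.0045), all with adjusted p of 0.75 or more with an estimated correlation. Among the control seeds of miRNAs not expected in these cells, miR-9 in Dicer (99.5) and miR-1 in Ago (99.3) also lay above the random range.

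**Figure D2:**
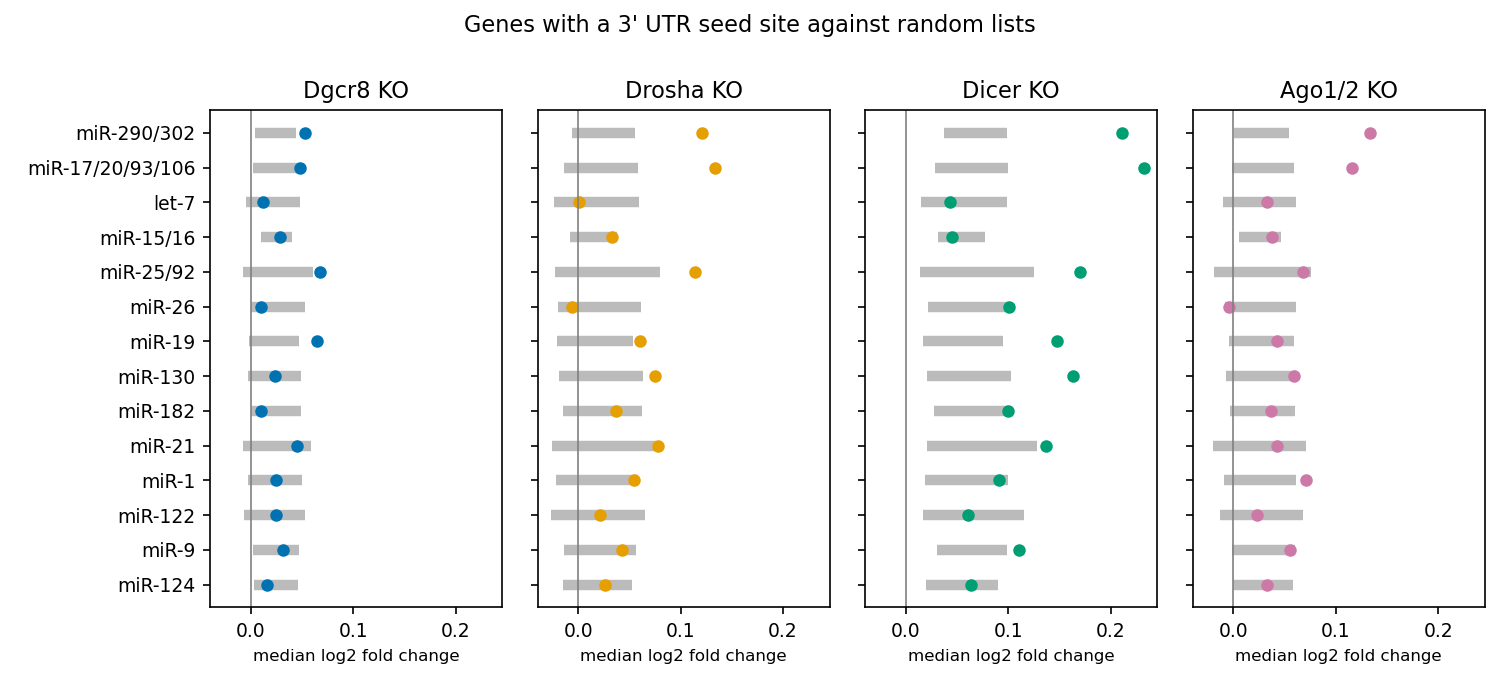
Median log2 fold change of genes with a 7mer-m8 site for each of 14 seed families, with 1 panel per knockout. Bars give the 95% range of 10000 random lists matched on 3' UTR length and expression, and the median for the miR-290 and miR-302 seed is 0.21 in Dicer against a range of 0.037 to 0.098.

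Differences between the knockouts were tested directly. Between Drosha and Dicer, the targeted gene Dicer1 missed the threshold (log2 2.72, SE 0.39, edgeR adjusted p = 0.095). Drosha and Dicer differed in 1 gene, Drosha itself (log2 -2.91, SE 0.33, adjusted p = 0.019), with 829 genes at an unadjusted p under 0.05, 67 genes called by DESeq2 and 0 by limma-voom. That count became 2 without the first Drosha library and 0 without either WT library, without the second Drosha library or without either Dicer library. Drosha and Ago differed in 5 genes, with Ago2 (log2 4.02), Anxa3, a calcium-dependent membrane binder (log2 3.23), and Parva, an adaptor of focal adhesions (log2 2.52), higher in Drosha, and Ctcfl (log2 -5.86) and Drosha (log2 -3.27) lower. The 5 became 10 and 2 without the first and second Drosha libraries, and 53 and 2 without the first and second Ago libraries. Dicer and Ago differed in 60 genes, 36 higher in Dicer, with Anxa3 (log2 3.81), Ago2 (log2 3.66), the peptidase Erap1 (log2 3.64) and Parva (log2 3.50) higher and Ctcfl (log2 -7.75), Pla2g1b (log2 -3.67), the retinoid-binding Crabp1 (log2 -3.42) and Stra8, which starts meiosis (log2 -3.40), lower in Dicer. The 60 became 25 and 15 without the first and second WT libraries, 4 and 14 without the first and second Dicer libraries, and 157 and 4 without the first and second Ago libraries. With a block for runs of library numbers the balance turned toward genes lower in Dicer. Crabp1, Erap1 and Stra8 lost their calls, as did Parva between Drosha and Ago. The second Ago library was alone in its run, so with that block these comparisons rest on the first Ago library. In limma-voom 111 genes were higher and 10 lower in Dicer.

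Between the libraries labelled Dgcr8 knockout and the Drosha knockout 55 genes differed, 44 of them lower in Dgcr8. Drosha (log2 2.88), the lysine-degrading enzyme Aass (log2 2.92), Pcyt1b (log2 2.56) and Amot (log2 2.38) were higher there, and Tmem92 (log2 -5.63) and the Y-linked Uba1y (log2 -5.29), Uty (log2 -5.27) and Ddx3y (log2 -4.95) were lower. Against the Dicer knockout 447 genes differed, 350 of them lower in Dgcr8, with the secreted Spink1 (log2 4.6) and Pla2g1b (log2 4.51), Tro (log2 3.8) and Steap1 (log2 3.50) higher and Tmprss3 (log2 -6.41), Cdh13 (log2 -6.21) and Chit1 (log2 -6.11) lower. Against the Ago knockout 53 genes differed, 39 of them lower in Dgcr8. The imprinted Mest (242 against 4.62 CPM, log2 5.78), Spink1 (log2 4.24), Arl14epl (log2 3.39) and Ago2 (log2 3.28) were higher and Tmem92 (log2 -5.80), Uty (log2 -5.23), Ctcfl (log2 -4.82) and Ddx3y (log2 -4.71) lower.

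The counts for these pairs moved with single libraries. Dgcr8 against Drosha gave 16 and 14 without the first and second WT libraries, 4 without the first Dgcr8 library, 19 and 23 without the Drosha libraries, and 20 and 9 without the Dicer libraries. Dgcr8 against Dicer gave 259 and 254 without the WT libraries, 108 without the first Dgcr8 library, and 12 and 225 without the Dicer libraries. Dgcr8 against Ago gave 26 and 22 without the WT libraries, 8 and 98 without the first and second Dgcr8 libraries, 31 without the first Drosha library, 26 and 23 without the Dicer libraries, and 26 without the second Ago library. Of the named genes called in these pairs, Drosha (Dgcr8 against Drosha) and Ago2 and Ctcfl (Dgcr8 against Ago) kept their calls under every alternative.

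Whole chromosomes differed between groups as well. Genes of chromosome 1 had a median log2 deviation from their own mean of 0.31 and 0.46 in the WT libraries and between -0.01 and -0.12 in the 8 others. Genes of chromosome 15 stood at -0.12 and -0.32 in WT and -0.15 and -0.28 in the Dgcr8 libraries, and between -0.0022 and 0.22 in the Drosha, Dicer and Ago libraries. Chromosome 1 held 5.59% of tested genes and 12.3%, 14.3% and 24.2% of those that fell in Drosha, Dicer and Ago, and chromosome 15 held 4.12% of tested genes and 12.1%, 7.31% and 8.76% of those that rose. The Y-linked Ddx3y, a helicase, stood at 0.199 CPM in the second Dgcr8 library and 5.95 CPM in the first, 32.9 and 10.4 CPM in WT, and between 86.4 and 156 CPM in the Drosha, Dicer and Ago libraries. Not all 5 Y-linked genes went this way, since Gm47283 stood at 109 and 53.4 CPM in the Dgcr8 libraries and 48.1 and 37.0 CPM in WT, and Uba1y at 1.75 CPM in the second Ago library and 2.86 and 1.91 CPM in WT.

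**Figure D3:**
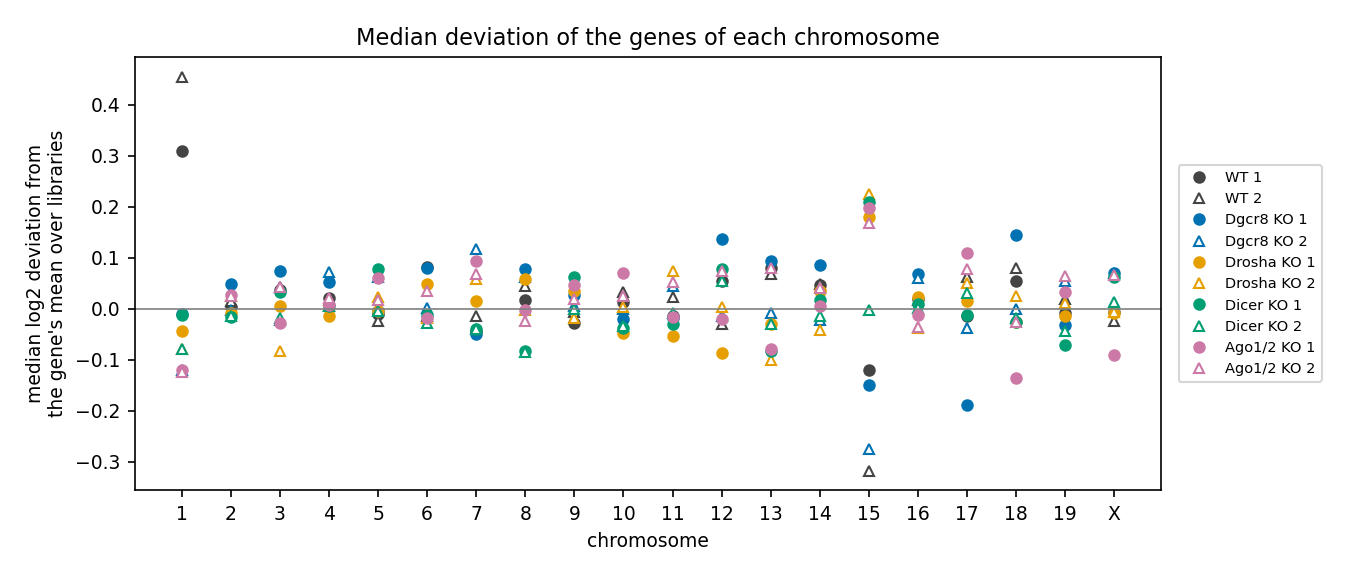
Median log2 deviation of genes over 10 CPM from their own mean over libraries, by chromosome, with filled circles for the first and open triangles for the second replicate of each group. Chromosome 1 reaches 0.31 and 0.46 in the WT libraries and lies at or below -0.01 in the others.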

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

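The tests of library depth on the primitive endoderm list, of WT material on abundant WT genes, of primitive endoderm cells, of loss of chromosome Y, and of depth against shallower libraries and on genes of 6 to 12 CPM were chosen after the result was seen, as were the libraries and chromosomes looked at; the other tests were written first. The differences below come from tests of the difference itself in edgeR, at an adjusted p under 0.05.

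Effects against the same WT libraries differed between knockouts. The libraries labelled Dgcr8 knockout differed from the Drosha knockout in 55 genes, with Drosha higher by 2.88 on the log2 scale. They differed from the Dicer knockout in 447 genes, with Dgcr8 higher by 1.05 and Dicer1 by 3.14. They differed from the Ago knockout in 53 genes, with Ago2 higher by 3.28. Drosha and Dicer knockouts differed in 1 gene, Drosha itself (log2 -2.91). Dicer1 stood higher in the Drosha than in the Dicer knockout but missed the threshold (log2 2.72, SE 0.39, edgeR adjusted p = 0.095). Drosha and Ago knockouts differed in 5 genes, with Drosha at -3.27 and Ago2 at 4.02. Dicer and Ago knockouts differed in 60 genes, with Dicer1 at -2.87 and Ago2 at 3.66. Groups of 2 libraries do not allow a test for a single library far from the rest.

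Primitive endoderm markers were high in WT and in the first Dgcr8 library and low elsewhere. Against depth, 11 members that were low in the second Dgcr8 library had a median of 1.29% of WT in the second Ago library, which is deeper than either WT library, although the sum over all 14 members there was 22.7% of WT and decides nothing. Cells of primitive endoderm type in the WT cultures and the first Dgcr8 culture remain a candidate explanation that its test cannot decide. In that library 90% of 10 core members stood within a factor of 2 of their median of 55.1% of WT. Genes unchanged from WT would lie in that range too. WT material in the first Dgcr8 library stays open only as a smaller share. By itself, such a share would not bring the core members to 55.1% of WT. For 10 of 3725 abundant WT genes the ratio lay far under 55.1%, Grb10 lowest at 6.64% and Myh9 next at 15.2%. A share of WT material near 55.1% would not leave these genes so low. Their number is at the bound set for exclusion and not past it. In addition, 119 genes higher in the second Dgcr8 library stood a median of 80.2% of the way to WT in the first (58.5% to 95.8%). Choosing those genes in the second library pushes that measure toward WT. The design gives no biological account that tells the genotype from the culture, and that was not tested.

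Chromosomes 1 and 15 shifted as wholes between groups, and on chromosome Y 4 of 5 genes stood lower in both Dgcr8 libraries than in both WT libraries. A bias of GC content and expression was excluded as the account, with chromosome 1 at -0.44 and chromosome 15 at 0.37 against matched random lists of -0.06 to 0.03 and -0.05 to 0.07. Extra or lost copies may account for the shifts, as 100% of 10 bins of chromosome 1 and 100% of 6 bins of chromosome 15 moved the same way. A lost chromosome Y in the second Dgcr8 culture stays open: all 5 Y-linked genes there stood at 47.9% of WT, but 53.4 of their 54.0 CPM lay in Gm47283, whose reads may come from elsewhere, and the other 4 stood at 0.853% (3 counts). Copy number was not measured, and counts cannot place the event before or after the knockout.

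The second Drosha library had 201 tested genes at 0. Depth was excluded as the whole account, since the first Drosha and second Dicer libraries, both shallower, had 22 and 59 such genes, and the most in any deeper library thinned to its total was 96, in the second WT library. That 96 met the bound set first, but not by its counting error, so depth as part of the account stays open. Genes above 1 CPM in each other library and at 0 in this one numbered 74, against 13 by the same measure in the second Dicer library. Among genes of 6 to 12 CPM the second Dicer library had 11 zeros and this one 27, too few to decide. Few distinct molecules behind the reads may account for them, since 4.18 reads per molecule, set on genes of 3 to 6 CPM, predicted 19 zeros (11 to 28) among genes of 6 to 12 CPM. A loss specific to this culture was not tested.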

How the results depend on the processing

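Thinning all libraries to the smallest total and leaving out genes of chromosomes 1, 15 and Y were chosen after the results were seen; the other alternatives were set before the data were examined. RLE, total-count and upper-quartile scaling, no filter (11011 genes) and the stricter filter (9504 genes) kept every count of genes within 1.5 times its value, and each scaling moved the median of all genes by less than 0.1 on the log2 scale. Of 215 called gene results 33 kept direction and call under every alternative run, and of 37 called list results 0 did, since the estimated correlation ended each list call. Spike-in totals and pseudocounts were not run, as the table holds no spike-ins and holds counts, and the fit to 2 groups has no value for the mean of the knockouts or for all 4.

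For the counts of genes, the order below is Dgcr8, Drosha, Dicer and Ago against WT, their mean, Dgcr8 against Drosha, Dicer and Ago, Drosha against Dicer and Ago, Dicer against Ago, and all 4, and the reported counts were 8, 378, 1220, 316, 776, 55, 447, 53, 1, 5, 60 and 5. DESeq2 gave 160, 972, 1874, 932, 1444, 310, 893, 359, 67, 142, 377 and 67. With limma-voom, Dgcr8 gave 15, Drosha 111, Ago 942, Dgcr8 against Drosha 27 and against Ago 436, Drosha against Dicer 0 (829 genes at an unadjusted p under 0.05 in edgeR) and against Ago 2, and Dicer against Ago 121. Fitting only the 2 groups compared gave 0 for Dgcr8, 3224 for Dicer, 536 for Ago, 10 and 28 for Dgcr8 against Drosha and Ago, 0 for Drosha against Dicer and 28 for Dicer against Ago. A test against a 1.5-fold change, stricter by construction, gave 4, 120, 604, 134, 253, 10, 192, 21, then 18 for Dicer against Ago and 1 for all 4. Thinning gave 5 for Dgcr8, 4 for Drosha against Dicer, 11 for Drosha against Ago and 2 for all 4. Without chromosomes 1, 15 and Y, Dgcr8 against Drosha gave 32, Drosha against Dicer 0 and Drosha against Ago 3. Except for the stricter test, the cause was not tested.

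The labels do not state that equal replicate numbers belong together. Outside Ago, library numbers ran from 28 to 31 in first replicates and from 37 to 41 in second replicates. The first Ago library was number 40. The replicate block and the correlations here took it as a first replicate, so their Ago values may be mispaired. Differences between replicates 1 and 2 correlated between groups with r of 0.061 to 0.29 across genes, above 0 for every pair of groups, so an effect shared by replicate number is not ruled out. A replicate block gave 14, 770, 1877, 738, 1410, 175, 779, 200, 6, 45 and 212, and 1 seed test (miR-17 in Dicer) in place of 2. A block for runs of library numbers, in which both Ago libraries fall outside the earliest run, gave 33, 951, 2168, 698, 1634, 207, 919, 387, 4, 16, 37 and 17. Library number 52, the second Ago library, was alone in its run. That block therefore absorbed it, and its Ago comparisons rest on the first Ago library. Beyond that the cause was not tested for either block.

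Leaving out 1 library at a time, with the lone library of a group assumed to vary like the other groups, gave 0 to 107 genes for Dgcr8, 1 to 514 for Drosha, 139 to 1503 for Dicer, 3 to 494 for Ago, 3 to 1100 for the mean, 4 to 77, 12 to 544 and 8 to 98 for Dgcr8 against Drosha, Dicer and Ago, 0 to 2 and 2 to 53 for Drosha against Dicer and Ago, 4 to 157 for Dicer against Ago and 0 to 52 for all 4. List tests ranged from 31 to 37. Correlations ranged from 0.38 to 0.70, 0.46 to 0.70 and 0.41 to 0.71 for Dgcr8 with Drosha, Dicer and Ago, 0.43 to 0.85 and 0.38 to 0.79 for Drosha with Dicer and Ago, and 0.60 to 0.81 for Dicer with Ago. One library fewer leaves 4 residual degrees of freedom, and beyond that the cause was not tested.

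List tests gave 0 with an estimated correlation and 15 with fry, and seed tests 0 with an estimated correlation and 7 with 8mer sites. Directions that reversed were those of Dicer1 in the Drosha knockout, from -0.01 to 0.0013 (RLE), 0.029 (total count), 0.024 (upper quartile), 0.0013 (DESeq2), 0.0043 (without WT replicate 2) and 0.46 (without Drosha replicate 1, and -0.72 without replicate 2), of Dicer1 in Ago to -0.15 (block of library numbers), of Drosha in Dgcr8 to -0.10 (without Dgcr8 replicate 2, and 0.61 without replicate 1), of Ago1 in Ago to -0.44 (without Ago replicate 1, and 0.90 without replicate 2), and of the ribosomal protein list in Ago (adjusted p = 0.55 without Ago replicate 2 and 1.6e-16 without replicate 1). None of these genes passed the test before, and the cause was not tested. The floor of the shallow libraries, 1.34 to 1.71 CPM, limits what can be said of genes that are near 0.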

Other observations

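The comparisons and the gene lists behind this part were fixed before the data were examined, while the members named here were picked from those lists after the result was seen. Tnrc6a and Tnrc6b, the scaffold proteins that link Ago to mRNA decay, rose in Drosha (log2 1.63 and 1.60), Dicer (log2 1.95 and 1.79) and Ago (log2 1.79 and 1.77), while the small RNA pathway list did not pass the test in Dicer or Ago. Lin28a, which blocks let-7 maturation and is itself a let-7 target, fell in Dicer (log2 -3.33, adjusted p = 0.0099), where the list of let-7 targets did not pass the test. Igf2bp2, another let-7 target, rose there (log2 1.09, adjusted p = 0.033).

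Some germline genes were called, although the germline list passed the test in none of the 4 groups. Fkbp6 (log2 4.39, adjusted p = 0.016) and Hormad1 (log2 3.51, adjusted p = 0.025), both needed in meiosis, rose in the Ago knockout, Rpl10l, a testis form of a ribosomal protein, rose in Drosha (log2 1.90) and Dicer (log2 2.16), and Mael, a piRNA pathway protein, fell in Dicer (log2 -1.46). Tdrkh fell in Drosha to 3 counts, a ratio of 14.1 with an interval of 4.79 to 68.8. Among growth factor genes Tgfb1 fell in Dicer (log2 -2.09) and Nodal rose in Ago (log2 1.97, adjusted p = 0.038). Among imprinted genes Ndn rose in Drosha (log2 2.20), and Peg3 rose in Dicer (log2 1.39) and Ago (log2 1.61). Alternatives were not run for Tnrc6a in Drosha. Of the other 18 calls given in this part, 4 stayed past the threshold without the first WT library, 0 without the second, 17 and 15 without the first and second Drosha libraries, 12 and 13 without the Dicer libraries, and 16 and 14 without the Ago libraries. All 18 stayed without either Dgcr8 library.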
